A study of Solanum lycopersicum with 15 samples.

How the data were processed

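Gene expression was measured in roots of tomato seedlings on one-colour Agilent arrays, with 3 arrays for each of control, cadmium, chromium, mercury and lead. Seeds germinated in metal-spiked soil in petri dishes and roots were taken after 7 days in darkness. The labels give 10 pooled seedlings per array. Samples were grouped by the treatment in the labels, and the replicate numbers were taken only to name the pools.

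The deposited scanner files came from Agilent Feature Extraction 10.7.3.1, and the processed signal is, per the file headers, a background-subtracted and detrended intensity with no scaling between arrays, in which low values were replaced by a surrogate. The mean spot signal and the local background are, per the file headers, raw intensity values. The other deposited columns that were used are flags of 0 or 1 per spot, per the file headers. The authors' value table is on the log2 scale and quantile normalized between the 15 arrays, with the same sorted values and a median of 8.01 in every column. The steps behind it are not stated. It was used as an alternative source only, and 12 of its columns followed the scanner files with Spearman's rho of 1.

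Spots marked non-uniform were left out (between 2 and 40 per array), spots of the same probe were averaged, and log2 processed signals were taken relative to the 75th percentile of each array. Of 43603 probes, 33528 well above background on all 3 arrays of at least 1 group were kept and 10075 were left out. The array names 33939 genes or transcripts. A gene name or description other than a clone, an unknown or a hypothetical protein was given for 3907 probes of 2553 genes, 2070 of them kept, while 13253 probes were described as Unknown. Of 758 gene symbols, 688 were found in the RefSeq gene table, and of 385 gene numbers 336. Genome positions were not used here. Phytochelatin synthase was not found by name.

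Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 15 arrays, 5 groups, no covariates), two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. The prior had 2.23 degrees of freedom. Comparisons were each metal against control, each pair of metals, the mean of the 4 metals against control, and an F test over the 4 metal contrasts. Probes passing in the same direction in all 4 metals, and Pearson correlations of log2 fold changes across probes, were set beside 20 simulations of unchanged groups that share the controls. Tables were read with the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9.

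The comparisons, the thresholds, the search terms of 32 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The lists as used are narrower than these terms. Weak similarity matches and clone library text were not searched, and some members were removed on reading their descriptions. Each list was tested in each metal with camera (preset correlation 0.01, 1 probe per gene, Benjamini-Hochberg over the lists of a metal), where at least 4 genes were measured, giving 22 lists a metal and 88 tests. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, were alternatives. In total 23 of 88 list tests passed with the preset correlation (11 in cadmium, 4 in chromium, 6 in mercury, 2 in lead), and with an estimated correlation those of heat shock proteins in chromium and mercury alone. Counts of members are given over all probes tested and, for the lists of each metal in the results, adjusted over the list alone where that count differs. Named genes were, for each metal, the 6 highest and the 6 lowest log2 fold changes among genes with a name that passed the test and had all 3 treated arrays on one side of the 3 controls, up to 2 passing members of each list with the smallest p, and IRT1, fer and the brightest metallothionein whatever their result. Across metals the rule took 6 genes passing in most metals, and between metals the 2 highest and 2 lowest. Where no array of a group was well above background, a fold change is given as a lower bound against the background of that group.

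Alternatives were normexp background correction (offset 50), median, quantile and spike-in scaling, no filter on dim probes or a filter on all arrays, keeping non-uniform spots, the value table, only the compared groups in the fit, trend and robust eBayes, the slide as a fixed or random block, the replicate number as a block, a fold threshold of 2 with adjusted or unadjusted p, the mean of a gene's probes in list tests, and leaving out each array. The labels tie no arrays of the same number together. Residuals of same-numbered arrays correlated with r = 0.26, 0.18 and 0.15 between control and cadmium and 0.35, 0.38 and 0.20 between control and lead, each over 0.1, which in no other comparison held for all 3 pairs. For these comparisons the values with the replicate number as a block are given where a call changed or a count moved by over 1.5 times. Added after seeing the data were the fits without control 1, cadmium 3 and mercury 1 together and normexp with outlying local backgrounds reset. Also added was a run of the lists as written, with the search terms as first fixed and no match or member removed. As a check, data were simulated with normal noise, independent between probes, with the same spread per probe in all groups and no slide effect. These settings meet the assumptions of limma, so they favour few false calls. With each group's own spread instead, simulated unchanged groups gave up to 69 probes passing in all 4 metals. The limma test was tested on the data with the same spread in all groups, with 200 changed probes per metal. It recovered 83.3%, 87.9%, 83.3% and 80.3% of log2 changes of 2 in cadmium, chromium, mercury and lead, 55.2%, 43.3%, 55.2% and 49.3% of log2 changes of 1 and 11.9%, 0%, 7.46% and 5.97% of log2 changes of 0.5, with 4, 3, 5 and 3 false calls.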

Results

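RNA from tomato roots was hybridised to 15 one-colour Agilent arrays. The roots came from seedlings germinated for 7 days in darkness in soil that held a metal salt or none. The 5 groups had 3 arrays each: control, cadmium (3.3 mg/kg), chromium (1.2 mg/kg), mercury (2.3 mg/kg) and lead (194.4 mg/kg). The labels give each dose as the same fraction of that metal's own median lethal concentration. Per the labels, each array measured the pooled roots of 10 seedlings. The labels leave open whether the 3 pools of a group came from separate dishes, so the limma p-values of single probes below measure the spread between pools. Camera p-values compare the genes of a list with the other genes. With the preset correlation they rest on the spread across genes. The arrays filled 4 slides. Slide 1 held the 3 control arrays and cadmium 1, slide 2 held cadmium 2, cadmium 3, chromium 1 and chromium 2, slide 3 held chromium 3 and the 3 mercury arrays, and slide 4 held the 3 lead arrays and no other.

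Between 68.6% and 85.3% of probes were well above background on an array, with 68.6% on cadmium 3 and 85.3% on cadmium 1. The median processed signal lay between 229.3 (cadmium 3) and 315.9 (lead 1) fluorescence units, and 0 spots were saturated. The number of arrays limits the precision, and the array files give no genome coordinates. Gene identities are the symbols, descriptions and transcript identifiers printed in the array files, many of them assigned by similarity. Log2 signals are relative to each array's 75th percentile, and changes are relative to that reference.

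One control array stood apart in the scanner files. There, control 1 had r = 0.945 across probes with each of the other control arrays, which had r = 0.989 with each other, and its highest r with any array was 0.952, with cadmium 1. In the authors' value table control 1 did not stand apart, with r = 0.994 and 0.987 with controls 2 and 3, which had r = 0.989 with each other. Of 40 measured shoot and photosynthesis markers, 30 were higher on control 1 than on each of the other 14 arrays. Transcripts of the carbon-fixing enzyme rubisco were among them, with the small chain 3B probe (AW037505) 8.58 higher on the log2 scale than the mean of the other arrays. The columns of control 1, cadmium 3 and mercury 1 in the authors' value table did not follow their scanner files, with Spearman's rho of 0.956, 0.979 and 0.982 across probes, against 1 for the other 12 arrays. The scanner file of control 1 was closer to the column of cadmium 1 (rho = 0.963) than to its own. Which of both sources belongs to the labelled sample is unknown for these 3 arrays, so the main counts below also appear without control 1, without these 3 arrays and from the value table.

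The cadmium comparison asked which root transcripts differed between soil with cadmium and control soil. Heat shock protein 90 (TA37068_4081), a chaperone that helps other proteins fold, had a log2 fold change of -2.27 ± 0.34 (SE, n = 3 pools per group, limma adjusted p = 0.0205), from a mean of 1.33 ± 0.65 (SD) in control to -0.94 ± 0.62 in cadmium. The chaperonin-60 beta subunit (TA35711_4081) fell by 1.17 ± 0.22, and ER24, an ethylene-responsive transcript, fell by 1.27 ± 0.23. Sulfite reductase (TA37692_4081), an enzyme of sulfate assimilation, rose by 0.85 ± 0.16, glutathione peroxidase 5 (DB720302), which removes peroxides, by 0.83 ± 0.18, and a putative zinc transporter (LOC100037509) by 0.78 ± 0.12. The cysteine proteinase transcript cyp-3 (Z48736) rose by 1.13 ± 0.23 and CmE8 (TA37942_4081) by 0.91 ± 0.19. With the replicate number as a block, glutathione peroxidase 5 and CmE8 had adjusted p = 0.0522 and 0.0535. Of the cytochrome P450 transcripts named CYP72A56, DB726954 rose by 0.87 ± 0.18 and TA54303_4081 by 1.53 ± 0.30, the latter well above background on 1 array of 3 in each group. Without control 1 sulfite reductase and DB726954 had adjusted p = 0.0513 and 0.0544. Transcripts of abz1 (-1.07 ± 0.20) and of the wall enzyme XTH-6 (TA54505_4081, -1.07 ± 0.21) fell. The iron transporter IRT1 (LOC543597), the iron-deficiency regulator fer and a metallothionein (LOC778300) had log2 fold changes of -0.11 ± 0.27, 0.28 ± 0.35 and 0.02 ± 0.17, with limma adjusted p = 0.857, 0.704 and 0.97.

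Among the gene lists in cadmium, 3 of 25 measured heat shock proteins fell, 0 rose and 22 did not pass the test (7 fell adjusted over the list alone). The list median was -0.41 (camera adjusted p = 3.2e-05, and adjusted p = 0.155 with an estimated correlation). Of 21 cytochrome P450s, 2 rose and 19 did not pass (4 rose adjusted over the list alone), with a list median of 0.53. Of 14 antioxidant enzymes 1 rose, and of 4 genes of sulfate uptake and assimilation 1 rose, with medians of 0.21 and 0.46. Without control 1 the sulfate median was 0.23 (camera adjusted p = 0.118). No single member passed among 12 glutathione S-transferases, 10 class III peroxidases, 10 pathogenesis-related proteins, 8 phenylpropanoid and lignin genes, 11 hypoxia and fermentation genes or 78 ribosomal proteins, whose medians were 0.39, 0.64, 0.98, 0.56, 0.39 and 0.20. Adjusted over the list alone, 3 pathogenesis-related, 4 phenylpropanoid and 2 hypoxia genes rose. The pathogenesis-related medians per array, relative to the mean of the 15 arrays, were 1.48 on cadmium 3, -0.04 on cadmium 2 and -0.41 on cadmium 1, against -0.78, -0.70 and -0.37 on the controls, and without cadmium 3 the list had a median of 0.48 (camera adjusted p = 0.0696). Glutathione S-transferases and phenylpropanoid genes had medians of 0.13 and 0.40 without cadmium 3 (adjusted p = 0.331 and 0.158). The phenylpropanoid list also lost the threshold without cadmium 2 (adjusted p = 0.0642) and, with cytochrome P450s and ribosomal proteins, without control 2 (0.421, 0.0572 and 0.0741). In the value table glutathione S-transferases and pathogenesis-related proteins had adjusted p = 0.122 and 0.0713, and without the 3 arrays named above these lists and the sulfate list had 0.471, 0.117 and 0.197. Camera placed these last 9 lists above the other genes. Its adjusted p-values were 0.00892 for cytochrome P450s, 0.00703 for antioxidant enzymes, 0.0135 for sulfate genes, 0.0132 for glutathione S-transferases, 0.00598 for peroxidases, 0.00892 for pathogenesis-related proteins, 0.0246 for phenylpropanoid genes, 0.0132 for hypoxia genes and 7.68e-05 for ribosomal proteins. In the same order, adjusted p = 0.155, 0.155, 0.282, 0.38, 0.155, 0.316, 0.385, 0.155 and 0.567 with an estimated correlation. Ribosomal proteins alone of these 9 lists stayed past the threshold with the slide as a fixed block (camera adjusted p = 0.000392), the glutathione S-transferase median became -0.04, and the others had adjusted p = 0.353, 0.052, 0.215, 0.367, 0.367, 0.79 and 0.052 in that order. Of 40 shoot and photosynthesis markers 0 passed, and their median of -0.77 (camera adjusted p = 0.00366, and adjusted p = 0.707 with an estimated correlation) became 0.22 without control 1 and 0.24 in the value table.

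In cadmium, 349 of 33528 probes passed the limma adjusted p of 0.05, 200 higher and 149 lower. The count was 710 without control 1, 25 without control 2, 759 without control 3, 135 without cadmium 1, 113 without cadmium 2, 8 without cadmium 3, 98 without the 3 arrays named above, 585 with the replicate number as a block and 4095 from the value table, where 36.3% instead of 57.3% were higher. With the slide as a fixed block, which left cadmium 1 as the only link to the control, 5 probes passed (4027 at an unadjusted p under 0.05), and within slide 1, with 1 cadmium array against 3 controls, the limma count was 0 (1423 at an unadjusted p under 0.05). The fixed-block fit gave -1.77 for HSP90 (TA37068_4081), -1.16 for ER24, -1.18 for the chaperonin-60 beta subunit and 1.13 for CmE8. It gave 0.63 for sulfite reductase and 0.61 for DB726954, and none of these genes passed the threshold. The spike-in scaling gave 116 probes with 77.6% higher.

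The chromium comparison asked the same of soil with chromium. Heat shock protein 90 (TA37068_4081) fell by 4.56 ± 0.34 on the log2 scale (SE, n = 3 pools per group, limma adjusted p = 0.000191), from a mean of 1.33 ± 0.65 (SD) in control to -3.23 ± 0.40 in chromium. Extensins, structural proteins of the cell wall, changed in both directions: Dif54 (-4.25 ± 0.89) and ext1 (-4.00 ± 0.89) fell, while Lemmi8 (LOC544158) rose by 2.40 ± 0.53 and Lemmi11 (LOC544159) by 2.18 ± 0.47. Le3OH-1, a gibberellin 3-hydroxylase transcript, rose by 4.54 ± 0.88, with 1 of 3 control arrays well above background, and XTH6, an enzyme that rejoins xyloglucan chains, rose by 2.00 ± 0.34. The iron transporter IRT1 fell by 1.46 ± 0.27 (limma adjusted p = 0.0157), while fer and the metallothionein LOC778300 had values of -0.55 ± 0.35 and -0.19 ± 0.17 (limma adjusted p = 0.436 and 0.604). Sulfite reductase rose by 0.89 ± 0.16, CO1 by 2.69 ± 0.53, the P-rich protein EIG-I30 by 2.05 ± 0.43 and CYP72A56 (TA54303_4081) by 2.09 ± 0.30, the latter with 1 of 3 control arrays well above background. Sn-1 (TA54846_4081) fell by 4.18 ± 0.88. The flowering regulator sp was at least 8.67-fold lower, with 0 chromium arrays well above background. The adjusted p-values of ext1, Lemmi8, Lemmi11 and sp without control 1 were 0.0503, 0.0574, 0.0727 and 0.0618. The fit with the slide as a fixed block gave -2.45 for Dif54, -2.18 for ext1, 1.52 for Lemmi8, 0.54 for sulfite reductase, 3.45 for EIG-I30 and 7.98 for Le3OH-1, none past the threshold.

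Of 25 heat shock proteins, 11 fell in chromium, 0 rose and 14 did not pass (16 fell adjusted over the list alone). The list median was -0.75 (camera adjusted p = 1.92e-12, and adjusted p = 0.0141 with an estimated correlation). Of 21 extensins and arabinogalactan proteins, 2 rose, 4 fell and 15 did not pass, with 7 and 8 adjusted over the list alone, a median of -0.35 and camera adjusted p = 0.345. Of 23 ethylene genes 1 fell, and that was ER21, which encodes a heat shock cognate protein of the chaperone class. The ethylene median was -0.28 (camera adjusted p = 0.038, and adjusted p = 0.337 with an estimated correlation), and -0.21 without control 1 (adjusted p = 0.0892). Of 10 class III peroxidases 0 passed (2 rose adjusted over the list alone) and 9 had positive values, with a median of 0.54 (camera adjusted p = 0.0359, and adjusted p = 0.458 with an estimated correlation). The peroxidase median was -0.19 with the slide as a fixed block, where ethylene and auxin genes had camera adjusted p = 0.449 and 0.0744. Of 27 auxin genes 1 rose (2 adjusted over the list alone), the auxin-regulated homolog BG125071, by 1.26 ± 0.28, and the median was 0.27 (camera adjusted p = 0.0329, and adjusted p = 0.683 with an estimated correlation). Without control 1 the auxin median was 0.09 (adjusted p = 0.0892). Without chromium 2 the peroxidase, ethylene and auxin lists had adjusted p = 0.106, 0.0911 and 0.106, and without chromium 3 the peroxidase and ethylene lists had 0.0505 and 0.102. Peroxidases also lost the threshold without control 2 (0.0874), and ethylene genes without control 3 (0.061) and in the value table (0.18). Cytochrome P450s had 3 of 21 members that rose, among them CYP72A58 (TA38908_4081, 1.01 ± 0.22, adjusted p = 0.054 without control 1), and a camera adjusted p of 0.138.

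In chromium, 1097 probes passed the limma test, 653 higher and 444 lower. The count was 1132 without control 1, 529 without control 2, 479 without chromium 1, 257 without chromium 2, 456 without chromium 3, 1287 without the 3 arrays named above, 709 with spike-in scaling and 4770 from the value table (44.5% instead of 59.5% higher). With the slide as a fixed block, which ties chromium to the control through cadmium 1 alone, limma called 0 probes (2474 at an unadjusted p under 0.05), and HSP90 TA37068_4081 had -3.72 (adjusted p = 0.168). No slide held both chromium and control arrays.

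The mercury comparison asked the same of soil with mercury. The extensin transcript Dif54 had a log2 fold change of -5.19 ± 0.89 (SE, n = 3 pools per group, limma adjusted p = 0.00613), from a mean of 1.00 ± 0.68 (SD) in control to -4.19 ± 0.25 in mercury, and ext1 one of -5.14 ± 0.89. Heat shock protein 90 (TA37068_4081) fell by 3.87 ± 0.34 and Lehsp100/ClpB, a chaperone that dissolves protein aggregates, fell by 1.86 ± 0.17. The iron-deficiency regulator fer fell by 2.29 ± 0.35 (limma adjusted p = 0.00323) and the metallothionein LOC778300, a small metal-binding protein, fell by 0.66 ± 0.17 (limma adjusted p = 0.0385), while IRT1 had -0.18 ± 0.27 (adjusted p = 0.718). Glycolate oxidase (AW931126), which forms hydrogen peroxide, rose by 2.08 ± 0.25 and sulfite reductase by 0.99 ± 0.16, while cytosolic ascorbate peroxidase APX1, which removes hydrogen peroxide, fell by 0.53 ± 0.11. Among transporters, the aquaporin PIP2 (TA38086_4081) fell by 1.98 ± 0.46, pip1 rose by 1.99 ± 0.49 and the phosphate transporter LePT2 fell by 1.13 ± 0.30, with pip1 and LePT2 at adjusted p = 0.0775 and 0.0679 without control 1. Nectarin 5 (TA52190_4081) rose by 6.65 ± 1.73, 20ox-1, a gibberellin 20-oxidase, by 2.34 ± 0.67 and a VTC2-like transcript (TA36796_4081) by 2.28 ± 0.59, with 1 of 3 control arrays well above background in each, and without control 1 their adjusted p-values were 0.0799, 0.131 and 0.0999. CO1 rose by 3.12 ± 0.53. The pollen actin-depolymerizing factor 2 probe (TA56746_4081) fell by 5.49 ± 1.26, as did the TSB probes TC239515 (-4.55 ± 0.79) and LOC543717 (-3.91 ± 0.73) and CBF3 (DV103683, -4.93 ± 1.16), of a family that regulates cold responses. The actin-depolymerizing factor and TSB probes had 1 of 3 mercury arrays well above background. Without control 1 CBF3 had -3.33. Under the fit with the slide as a fixed block, Dif54 had -3.41, ext1 -3.14, fer -1.47, sulfite reductase 0.60, PIP2 -0.24 and LePT2 -0.51. The actin-depolymerizing factor probe had -1.56, TC239515 -2.83, LOC543717 -2.24, CBF3 -3.01, APX1 -0.84 and 20ox-1 4.46. IRT1 had -1.12, and none of these passed the threshold.

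Of 25 heat shock proteins, 13 fell in mercury, 0 rose and 12 did not pass (17 fell and 1 rose adjusted over the list alone). The list median was -0.73 (camera adjusted p = 1.52e-09, and adjusted p = 0.0361 with an estimated correlation). Of 21 extensins and arabinogalactan proteins, 8 fell, 0 rose and 13 did not pass (11 fell adjusted over the list alone), with a median of -0.94 (camera adjusted p = 0.00256, and adjusted p = 0.242 with an estimated correlation). Of 23 ethylene genes, 5 fell and 18 did not pass (7 fell and 1 rose adjusted over the list alone), with ER21 at -2.82 ± 0.38 and the ethylene-forming oxidase aco5 at -2.54 ± 0.61 (adjusted p = 0.0701 without control 1). These became -1.30 and -0.22 with the slide as a fixed block. The ethylene median was -0.35 (camera adjusted p = 0.0135, and adjusted p = 0.219 with an estimated correlation). Of 27 auxin genes, 4 rose, among them IAA1 by 1.02 ± 0.24, and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.0156, and adjusted p = 0.78 with an estimated correlation). Of 17 histones 1 fell (0 adjusted over the list alone), H3 (TA36276_4081, -0.91 ± 0.25, adjusted p = 0.0868 without control 1), and 16 had negative values, with a median of -0.41 (camera adjusted p = 0.00823, and adjusted p = 0.752 with an estimated correlation). Of 78 ribosomal proteins 3 fell (1 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0135, and adjusted p = 0.78 with an estimated correlation), and the value table gave a median of -0.02 with the opposite camera direction. Of 12 glutathione S-transferases, 1 rose and 3 fell (1 and 4 adjusted over the list alone), among them TA56135_4081 (-1.04 ± 0.22), and of 14 antioxidant enzymes 3 fell (5 fell and 2 rose adjusted over the list alone), with camera adjusted p = 0.322 and 0.319. Ethylene genes, extensins and arabinogalactan proteins, and histones had camera adjusted p = 0.539, 0.659 and 0.39 with the slide as a fixed block. Without control 1 the medians of extensins and arabinogalactan proteins, auxin genes, ribosomal proteins and histones were -0.73, 0.17, -0.06 and -0.25 (camera adjusted p = 0.0566, 0.0566, 0.756 and 0.0677). In the value table extensins and arabinogalactan proteins, auxin genes and histones had adjusted p = 0.115, 0.0741 and 0.0563, and without mercury 3 ribosomal proteins had 0.205.

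In mercury, 2891 probes passed the limma test, 1433 higher and 1458 lower. The count was 2645 without control 1, 1481 without mercury 1, 1925 without mercury 2, 962 without mercury 3, 2077 without the 3 arrays named above, 1673 with spike-in scaling and 6746 from the value table. With the slide as a fixed block, which reaches the control through chromium 3 and cadmium 1 alone, limma called 0 probes (1820 at an unadjusted p under 0.05), and 59 of the 2891 had the opposite sign. No slide held both mercury and control arrays.

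The lead comparison asked the same of soil with lead. The wall-loosening beta-expansin EXPB2 rose by 4.02 ± 1.08 (SE, n = 3 pools per group, limma adjusted p = 0.0171), from a mean of -5.31 ± 0.64 (SD) in control to -1.29 ± 0.50 in lead, XET4 by 3.08 ± 1.01 (adjusted p = 0.0545 with the replicate number as a block), XTH6 by 2.28 ± 0.34 and the pectin-degrading TAPG4 by 3.23 ± 0.76. Heat shock protein 90 (TA37068_4081) fell by 4.38 ± 0.34 and the heat shock cognate ER21 fell by 3.26 ± 0.38. The iron transporter IRT1 fell by 1.47 ± 0.27 (limma adjusted p = 0.00297) while its regulator fer rose by 1.28 ± 0.35 (adjusted p = 0.0187), and the metallothionein LOC778300 had -0.19 ± 0.17 (adjusted p = 0.421). The nitrate transporter NRT2;1 rose by 2.20 ± 0.36, the putative zinc transporter LOC100037509 by 1.13 ± 0.12, sulfite reductase by 1.01 ± 0.16 and glutathione peroxidase 5 by 1.11 ± 0.18. LeCBF1 (-5.22 ± 0.92), CBF3 (DV103683, -5.12 ± 1.16) and the salt-responsive SlSRG2 (-4.31 ± 1.00) fell, with SDs of 2.11, 2.79 and 2.42 among the controls and values of -4.03, -3.52 and -2.93 without control 1. The carbonic anhydrase ca3 was at least 12.8-fold lower and a wound-induced protein (TA43398_4081) at least 10.1-fold lower, with 0 lead arrays well above background for either. Chitinase (LOC544146) rose by 2.96 ± 0.77, a dehydrin-like protein (TC245073) by 2.02 ± 0.44, Le3OH-1 by 3.84 ± 0.88 and the anthocyanin regulator An2 by 3.80 ± 1.07, the latter pair with 1 of 3 control arrays well above background.

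Of 25 heat shock proteins, 17 fell in lead, 0 rose and 8 did not pass (17 fell and 1 rose adjusted over the list alone). The list median was -0.83 (camera adjusted p = 2.17e-07, and adjusted p = 0.083 with an estimated correlation). Of 78 ribosomal proteins, 40 rose, 3 fell and 35 did not pass (45 rose and 6 fell adjusted over the list alone), among them 60S L12 (TA37642_4081) by 0.69 ± 0.12. The ribosomal median was 0.38 (camera adjusted p = 4.22e-07, and adjusted p = 0.539 with an estimated correlation). Camera's direction was the same under every scaling tried. A scaling by a constant per array shifts the list and the other genes alike, so this tests little. Of 21 expansins and xyloglucan enzymes, 7 rose, 2 fell and 12 did not pass (7 and 2 adjusted over the list alone), with camera adjusted p = 0.178, and adjusted p = 0.664 with an estimated correlation. The list of 10 pathogenesis-related proteins had 4 that rose, that of 10 class III peroxidases 3 (4 adjusted over the list alone), that of 21 cytochrome P450s 6 and that of 11 hypoxia and fermentation genes 4, with 1 that fell. Camera gave these 4 lists adjusted p = 0.0526, 0.0526, 0.0902 and 0.0769. Of 23 ethylene genes 6 fell, among them the receptor ETR5 (-1.15 ± 0.16), and 0 rose (camera adjusted p = 0.0769). Of all probes tested, 28.9% passed in lead, higher or lower, and member counts near that share are no trait of a list.

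In lead, 9699 probes passed the limma test, 4704 higher and 4995 lower. The count was 12548 without control 1, 6129 without control 2, 4990 without lead 1, 5947 without lead 3, 12976 without the 3 arrays named above and 17401 from the value table. Lead and slide 4 cannot be told apart, because no other group lay on that slide and no fit with the slide as a fixed block gives a value for lead. With spike-in scaling the median log2 fold change of all probes was 0.28 instead of 0.00 in lead against control and -0.25 in each of cadmium, chromium and mercury against lead, instead of 0.01, 0.05 and 0.07, and 82.2% instead of 48.5% of 11537 probes were then higher in lead.

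**Figure D1:**
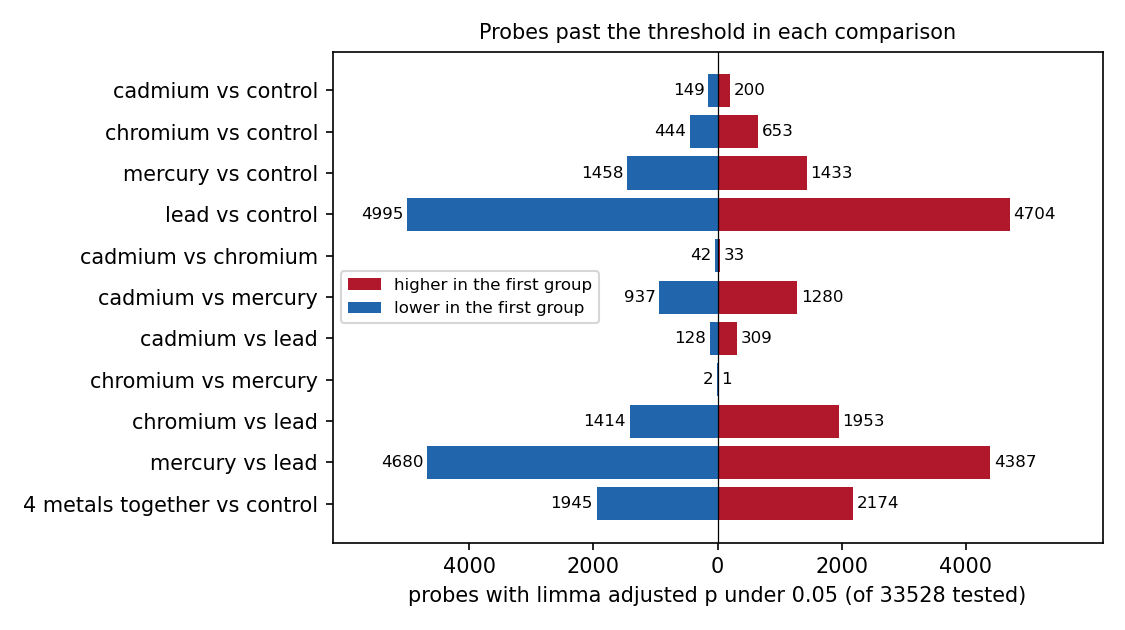
Probes with a limma adjusted p under 0.05 in each comparison, with bars to the right for probes higher in the first group and to the left for probes lower, and the count at each bar. Lead against control gave 4704 higher and 4995 lower probes, and chromium against mercury gave 1 and 2.

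Some heat shock transcripts were lower in all 4 metals. Of 25 measured heat shock proteins, 3 passed as lower in cadmium, 11 in chromium, 13 in mercury and 17 in lead. These counts rise with the share of all probes that passed, which was 1.04%, 3.27%, 8.62% and 28.9%. Adjusted over the list alone, 7, 16, 17 and 17 fell, with medians over all arrays of -0.41, -0.75, -0.73 and -0.83, so chromium, mercury and lead were close. With an estimated correlation the list had camera adjusted p = 0.155, 0.0141, 0.0361 and 0.083. HSP90 (TA37068_4081) had log2 fold changes of -2.27 in cadmium, -4.56 in chromium, -3.87 in mercury and -4.38 in lead, and the probe with the symbol HSP90 had -2.21, -4.35, -3.67 and -4.24. In the same order, ER24 had -1.27, -2.06, -2.14 and -1.67, Lehsp100/ClpB -0.88, -1.40, -1.86 and -1.35, and the chaperonin-60 beta subunit -1.17, -1.30, -1.36 and -1.44, with SEs between 0.17 and 0.38. Cullin 1C (BP895717), of a family that marks proteins for breakdown, fell by 2.16 ± 0.41 in cadmium and was at least 3.59-fold, 2.46-fold and 2.80-fold lower in chromium, mercury and lead, where 0 arrays were well above background. Of the named genes, 19 passed in the same direction in 4 metals, 34 in 3 and 105 in 2. The heat shock medians per array were 0.71, 0.66 and 0.37 in control, 0.39, 0.15 and 0.16 in cadmium, -0.12, -0.22 and -0.15 in chromium, -0.34, -0.33 and -0.33 in mercury and -0.54, -0.46 and -0.37 in lead, relative to the mean of the 15 arrays. The order of the groups follows the order of the slides. Within slide 2 the cadmium arrays (0.15 and 0.16) lay above the chromium arrays (-0.12 and -0.22). By these medians per array chromium 3, on slide 3, lay at -0.15 between the other chromium arrays and above the mercury arrays. The list medians in cadmium, chromium and mercury were -0.28, -0.44 and -0.59 with the slide as a fixed block (camera adjusted p = 0.0142, 4.59e-06 and 0.000129 with the preset correlation), all tied to the control through cadmium 1. Within slide 1 the median of that single array against the 3 controls was -0.28, with 18 of 25 genes lower, while its list median of 0.39 lay above that of control 3 (0.37). Set against the cadmium arrays on slide 2, cadmium 1 had a heat shock median of 0.34. Chromium 3, on slide 3, had one of -0.07 against the chromium arrays on slide 2. Within slide 2 the median of cadmium against chromium was 0.25, and within slide 3 that of chromium against mercury was -0.06. There 13 of 25 genes were lower in chromium, so gene by gene chromium 3 did not lie above mercury, unlike in the medians per array. The medians were negative in all 4 metals under each of the scalings tried and without control 1.

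**Figure D2:**
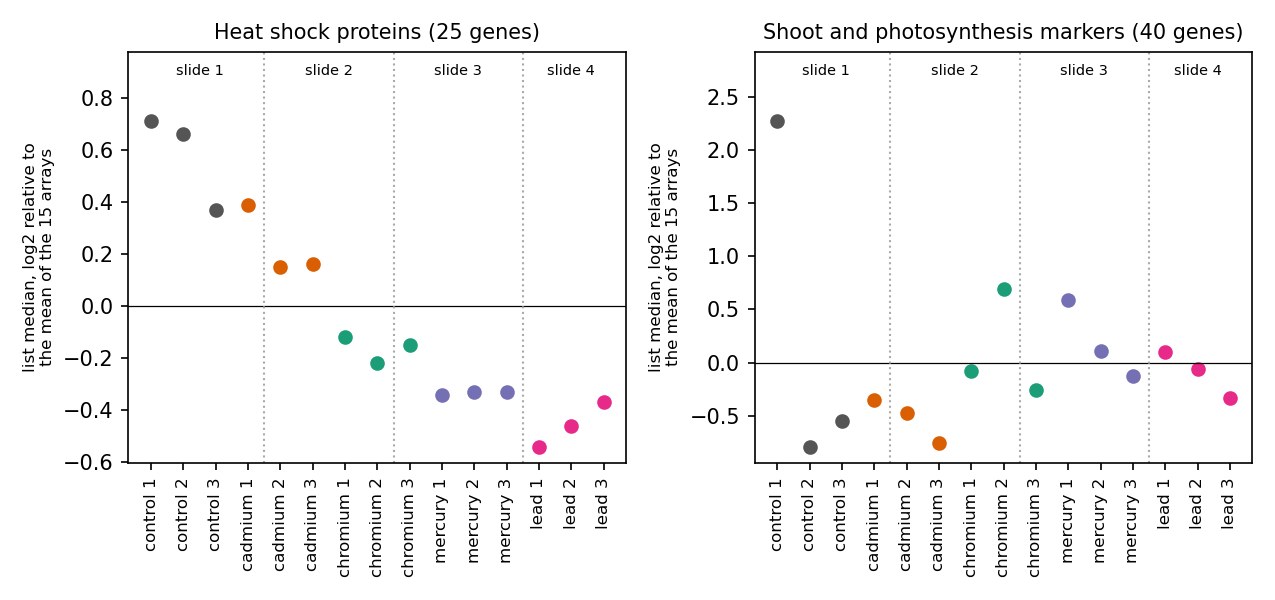
Median log2 signal of the heat shock list (25 genes, left) and of the shoot and photosynthesis list (40 genes, right) on each array, relative to the mean of the 15 arrays, with 1 point per array coloured by group and dotted lines between the slides. The heat shock medians lie between 0.71 on control 1 and -0.54 on lead 1, and the shoot median of control 1 is 2.27.

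In total 190 probes passed in the same direction in all 4 metals, 96 higher and 94 lower. Lists drawn independently would share 0.0361 probes, and simulated groups without a metal effect that share the same 3 controls gave up to 69 in 20 simulations. Each simulated group had its own spread per probe, with noise independent between probes, while the fit took the same spread for all groups. The 69 thus mixes shared controls with unequal spreads. The observed count of 190 became 314 without control 1, 19 without control 2 and 387 without control 3. It was 8 without cadmium 3 and between 61 and 113 without any other single array. It was 69 without the 3 arrays named above, 1295 from the value table and 64 with spike-in scaling. Across probes, which are not independent replicates, log2 fold changes correlated between metals with r from 0.45 (mercury and lead) to 0.77 (chromium and mercury). Simulated groups sharing the controls gave r from 0.66 to 0.75. The observed covariances of 0.156 to 0.261 exceeded the simulated 0.105 by 0.051 to 0.156. With 3 control arrays the controls cannot be split so that each metal has its own, so the part due to shared controls remains open.

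**Figure D3:**
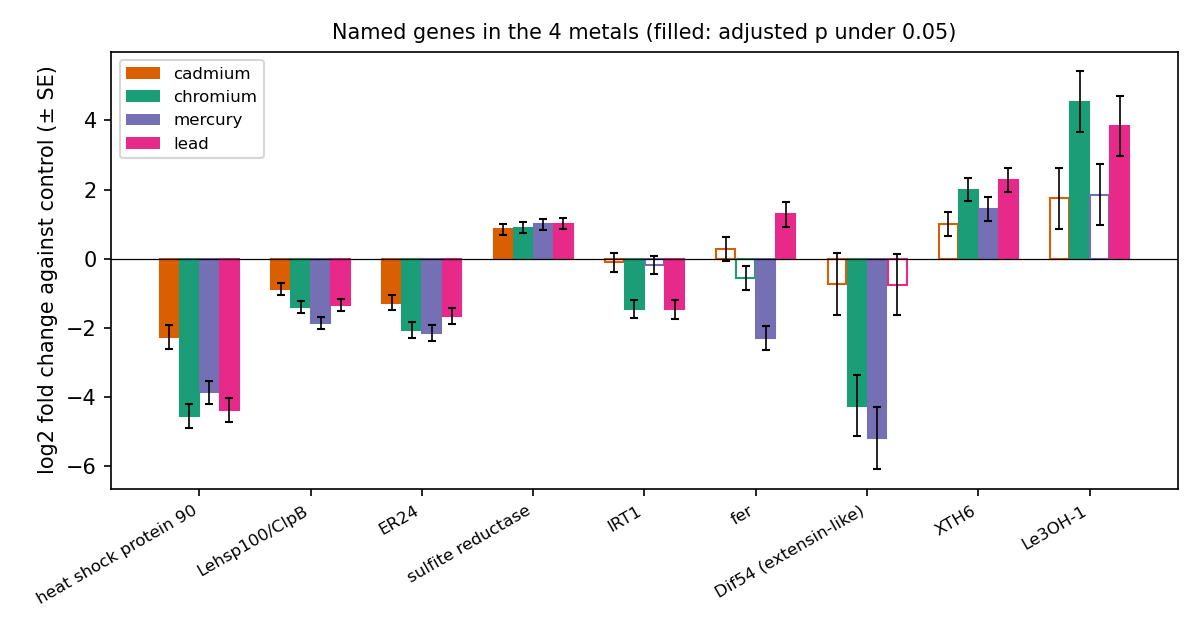
Log2 fold change against control (bars, with the SE as error bars, n = 3 pools per group) of 9 named genes in the 4 metals, filled where the limma adjusted p was under 0.05. HSP90 (TA37068_4081) lies between -2.27 and -4.56, and fer is filled at -2.29 in mercury and at 1.28 in lead.

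Comparisons between metals asked where the responses themselves differed, at doses that differ between metals. The iron-deficiency regulator fer was lower in mercury than in lead (-3.58 ± 0.35, SE, n = 3 pools per group, limma adjusted p = 0.000459), lower in chromium than in lead (-1.84 ± 0.35) and higher in cadmium than in mercury (2.58 ± 0.35). IRT1 was higher in mercury (1.29 ± 0.27) and in cadmium (1.36 ± 0.27) than in lead, and the metallothionein LOC778300 higher in cadmium than in mercury (0.67 ± 0.17). These genes were singled out between metals after their values were seen. The ACC synthase ACS2, an enzyme of ethylene synthesis, was higher in mercury than in lead by 4.19 ± 1.27 and ACS8 lower (-5.20 ± 1.19; SE, n = 3 pools per group, limma adjusted p = 0.0295 and 0.00924), with 1 of 3 mercury arrays well above background for ACS8. The carbonic anhydrase ca3 was at least 20.8-fold higher in mercury, 8.61-fold in cadmium and 6.77-fold in chromium than in lead. Chromium had LeCBF1 higher than lead by 3.96 ± 0.92 and ACS8 (-4.99 ± 1.19, with 1 of 3 chromium arrays well above background) and ext1 (-3.93 ± 0.89) lower. Cadmium had ext1 higher than mercury by 4.87 ± 0.89 and the pollen actin-depolymerizing factor 2 probe by 4.71 ± 1.26, while CO1 (-2.83 ± 0.53) and the aquaporin pip1 (-2.37 ± 0.49) were lower. That actin-depolymerizing factor probe was also lower in mercury than in lead (-5.64 ± 1.26). With the slide as a fixed block, cadmium against mercury had 4.02 for ext1, 2.52 for that probe, -4.38 for CO1 and -3.18 for pip1, none past the threshold. Cadmium had TPX2 higher than chromium by 2.74 ± 0.47 and HSP90 (TA37068_4081) by 2.29 ± 0.34. Glycolate oxidase (-1.44 ± 0.25) and digalactosyldiacylglycerol synthase (TA53897_4081, -1.13 ± 0.20), an enzyme of plastid lipids, were lower. In the same order the fixed-block fit gave 2.68, 1.95, -1.55 and -1.09, none past the threshold. Against lead, cadmium had the wound-induced TA43398_4081 at least 3.01-fold higher and the homeodomain gene BL3 (-1.52 ± 0.30) and pathogenesis-related protein 1 (BG129638, -1.17 ± 0.21) lower. Between chromium and mercury no gene with a name passed, and the 3 probes that did, named here after their values were seen, were transcripts BI207077 (1.86 ± 0.20), BW687410 (-2.23 ± 0.28) and AK322515, well above background on 3 mercury arrays and 0 chromium arrays.

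The limma counts were 9067 for mercury against lead (4387 higher, 4680 lower), 3367 for chromium against lead (1953 and 1414), 2217 for cadmium against mercury (1280 and 937), 437 for cadmium against lead (309 and 128), 75 for cadmium against chromium (33 and 42) and 3 for chromium against mercury (1 and 2). From the value table they were 14975, 9530, 7429, 4917, 941 and 515. Within slide 2 cadmium against chromium (2 arrays against 2) gave 0 limma calls (3202 at an unadjusted p under 0.05), and within slide 3 chromium against mercury (1 array against 3) gave 0 (3171), with too few arrays for these counts to show that the groups agree. The fit with the slide as a fixed block gave 2 for cadmium against chromium, 4 for cadmium against mercury and 18 for chromium against mercury, while lead could not be separated from slide 4. Under spike-in scaling the share higher was 14.3% instead of 48.4% in mercury against lead, 14.5% instead of 58% in chromium against lead, 11.3% instead of 70.7% in cadmium against lead and 27.1% instead of 44% in cadmium against chromium. Mercury against lead gave 5358 without mercury 1, 5002 without mercury 3, 4154 without lead 1 and 5141 without lead 3. Chromium against lead gave 610 without chromium 1, 631 without chromium 2, 534 without lead 1 and 655 without lead 3. Cadmium against mercury gave 275 without cadmium 1, 974 without cadmium 3, 439 without mercury 1 and 216 without mercury 3. Cadmium against lead gave between 26 (without lead 3) and 269 (without lead 2) when cadmium 1, 2 or 3 or lead 1, 2 or 3 was left out. Cadmium against chromium gave 2 without cadmium 1, 25 without cadmium 3 and 6, 1 and 3 without chromium 1, 2 and 3. Chromium against mercury gave 5, 0 and 0 without chromium 1, 2 and 3 and 1, 1 and 0 without mercury 1, 2 and 3, where the 0 counts had 2027, 2076 and 1993 probes at an unadjusted p under 0.05.

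The mean of the 4 metals was set against the control. A strong change in 1 metal can carry this contrast, so a probe that passes need not change in all 4, and 190 probes passed in the same direction in each metal. All control arrays lay on slide 1, with cadmium 1 as the only metal array beside them. The fit with the slide as a fixed block gave no value for this contrast. Here 4119 probes passed the limma test, 2174 higher and 1945 lower, with 4470 as the highest count and 1961, without control 2, as the lowest when any single array was left out. The value table gave 11199, with 41.1% instead of 52.8% higher, and spike-in scaling gave 71.6% higher. The limma F test for any difference among the 5 groups passed 9139 probes, and 5999 without mercury 1, 4864 without mercury 3, 3713 without lead 1 and 3730 without lead 3.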

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

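Counts of probes past the limma threshold are given in a fixed order: cadmium, chromium, mercury and lead against control, cadmium against chromium, mercury and lead, chromium against mercury and lead, mercury against lead, the 4 metals together, any difference among the 5 groups, and shared by all 4 metals. The main counts were 349, 1097, 2891, 9699, 75, 2217, 437, 3, 3367, 9067, 4119, 9139 and 190. The settings without the 3 arrays that differ from the value table, with outlying backgrounds reset and with gene lists as written were chosen after seeing the data. Where a count moved by over 1.5 times, the cause was not tested unless one is named.

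The normexp background gave 2, 55, 286, 1990, 1, 30, 2, 0, 193, 646, 514, 502 and 2. A few spots with an outlying local background drove its fit, as on mercury 3, where 3 such spots gave a fitted background mean of -1005.1, and -12.2 after reset. With normexp, outlying backgrounds reset, the counts were 487, 1002, 2758, 9601, 77, 1945, 457, 1, 3646, 8708, 3937, 8898 and 252. Spike-in scaling gave 116, 709, 1673, 11537, 48, 973, 1053, 0, 5278, 9875, 3091, 8956 and 64. No filter on dim probes, which adds probes to the adjustment, gave 105, 611, 1910, 8259, 1, 1021, 150, 0, 1906, 7613, 3026, 6333 and 70. Where chromium against mercury gave 0 limma calls, 1282, 2536 and 3323 probes had an unadjusted p under 0.05 in these 3 settings. Probes well above background on every array gave 1 for chromium against mercury, as did eBayes with trend and robust. The authors' value table gave 4095, 4770, 6746, 17401, 941, 7429, 4917, 515, 9530, 14975, 11199, 19152 and 1295. With only the groups compared in the fit, which leaves fewer arrays for the spread, the counts were 0, 59, 434, 3891, 1, 199, 96, 12, 3660 and 10622, and 0 were shared by all 4 metals. The cadmium count of 0 had 3122 probes at an unadjusted p under 0.05. A fit with only 2 groups gives no value for the 4 metals together or the F test.

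The slide as fixed block gave 5, 0 and 0 for cadmium, chromium and mercury against control, 2 and 4 for cadmium against chromium and mercury and 18 for chromium against mercury. It gives no value for lead, for the F test or for counts that need lead. The slide as random block gave 1267, 4123, 8448, 14578, 74, 6075, 3376, 17, 8509, 13709, 8842, 18049 and 681, with a consensus correlation of -0.14 between arrays of a slide. Control, mercury and lead each lay on a single slide, so this fit cannot separate slide from group. A negative correlation is no measure of spread between slides, and it narrows the standard errors of contrasts between slides. The higher counts therefore do not show that allowing for the slide strengthens the calls. The replicate block gave 585 for cadmium against control, 158 for cadmium against chromium and 723 for cadmium against lead, with the other counts within 1.5 times. As a check on that block, correlations of residuals between arrays of the same number in different groups had a median of 0.08 (between -0.22 and 0.38, with 14 of 30 over 0.1), against -0.04 for other pairs, and 8 of 15 arrays had their highest r with their own number. For cadmium and lead against control, where all 3 pairs were over 0.1, the replicate block ended the calls of glutathione peroxidase 5 and CmE8 in cadmium and of XET4 in lead and changed no other call of a named gene or list past the threshold. An adjusted p and fold of 2, a stricter rule by construction, gave 172, 532, 1296, 2913, 60, 726, 215, 3, 914, 2720, 1052, 3193 and 90. An unadjusted p and fold of 2 gave 1013, 1419, 2329, 3493, 580, 1822, 1147, 786, 1686, 3111, 1555, 4233 and 334. Without the 3 arrays that differ from the value table the counts were 98, 1287, 2077, 12976, 58, 1006, 711, 10, 6621, 9045, 4476, 9886 and 69. Quantile scaling, median scaling and keeping non-uniform spots left all these counts within 1.5 times.

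Leaving out each array of the compared groups in turn gave 8 (without cadmium 3) to 759 (without control 3) for cadmium, 257 (without chromium 2) to 1447 (without control 3) for chromium, 962 (without mercury 3) to 2693 (without control 3) for mercury and 4990 (without lead 1) to 12548 (without control 1) for lead against control. It gave 1 (without chromium 2) to 78 (without cadmium 2) for cadmium against chromium, 216 (without mercury 3) to 2543 (without cadmium 2) for cadmium against mercury and 26 (without lead 3) to 269 (without lead 2) for cadmium against lead. Chromium against mercury gave 0 (without chromium 2, chromium 3 or mercury 3) to 5 (without chromium 1), chromium against lead 534 (without lead 1) to 4411 (without lead 2) and mercury against lead 4154 (without lead 1) to 9090 (without lead 2). The 4 metals together gave 1961 (without control 2) to 4470 (without control 1), any difference 3713 (without lead 1) to 13434 (without control 1), and 8 (without cadmium 3) to 387 (without control 3) were shared by all 4 metals. The median correlation of log2 fold changes between metals, 0.66, lay between 0.60 (without chromium 3) and 0.75 (without control 3).

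Of 23 list tests past the threshold, camera with estimated correlation kept 2, fry kept 12, and the authors' value table kept 15, lost 6 and reversed 2. The gene lists as written, with the search terms as first fixed, kept 21 and lost 2. Over all 88 tests 18 passed with fry and 32 in the authors' values. The heat shock lists of chromium and mercury were past the threshold in every setting that gave them a value. Over all settings, called lists kept direction and threshold in 477 of 573 values, lost the threshold in 90 and reversed in 6. Without control 1, 7 of the 23 lists lost the threshold and 1 reversed, 9 lost it and 1 reversed without the 3 arrays that differ from the value table, and with the slide as fixed block 13 of 21 lost it and 2 reversed. Without chromium 2 and chromium 3, 3 and 2 of the 4 chromium lists lost it, and without cadmium 2 and cadmium 3, 1 and 3 of the 11 cadmium lists did. Called named genes did so in 2539 of 3291 values, lost the threshold in 746 and reversed in 6, with 116 of those losses under the normexp background and 92 with the slide as fixed block, where 0 of 93 stayed past it. Of 142 called named genes against control, 21 lost the threshold without control 1, 49 without control 2 and 15 without control 3. Among those of each metal, the losses without its replicates 1, 2 and 3 were 21, 16 and 23 of 27 in cadmium, 18, 24 and 17 of 33 in chromium, 24, 14 and 27 of 53 in mercury and 16, 6 and 18 of 69 in lead, comparisons between metals included. Directions reversed as follows, with the cause not tested beyond the settings named. For shoot and photosynthesis markers in cadmium, the authors' value table gave 0.24, the fit without the 3 arrays that differ from the value table gave 0.31, and leaving out 1 array gave between -1.39 (without control 2) and 0.22 (without control 1). For ribosomal proteins in mercury the authors' value table gave a median of -0.02 and the opposite camera direction. With the slide as fixed block, glutathione S-transferases in cadmium had -0.04, class III peroxidases in chromium -0.19, fer in chromium 0.21 and an expansin (TA55686_4081) in mercury 0.00. Under the normexp background, in mercury TA40272_4081 had 0.55, TA53576_4081 0.78, DB727620 0.60, IRT1 (LOC543597) 0.55 and Cullin 1C (BP895717) 0.20, and in lead TA40272_4081 had 0.27. The metallothionein LOC778300, never past the threshold in cadmium or lead, had -0.03 in cadmium under the normexp background, -0.02 with outlying backgrounds reset, -0.01 with the slide as random block, -0.09 without the 3 arrays that differ from the value table and -0.12 to 0.14 on leaving out 1 array. In lead it had 0.11 under quantile scaling, 0.09 under spike-in scaling and 0.04 in the authors' value table. IRT1 in cadmium lay between -0.23 and 0.06 on leaving out 1 array. Probes not well above background in a group limit fold changes to lower bounds there.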

Other observations

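The tests of explanations and of the heat shock list over regroupings were chosen after the results were seen, while the counts over other splits of the samples were planned before.

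In lead, the nitrate list had 2 of 6 genes that rose (4 adjusted over the list alone), NRT2;1 and the ammonium transporter AMT2 (0.99 ± 0.23), and 2 that fell, while in mercury glutamine synthetase (TA46152_4081), which fixes ammonium, fell by 1.38 ± 0.26 (camera adjusted p = 0.425 and 0.245). Jasmonate genes had 3 of 14 that rose in lead, with 12-oxophytodienoate reductase (BE450306) at 0.94 ± 0.19, and 0 past the test in the other metals (camera adjusted p = 0.795 in lead). Their median in lead was -0.07, with 8 of 14 lower. Of all probes tested, 28.9% passed in lead, against 1.04%, 3.27% and 8.62% in cadmium, chromium and mercury. More passing members in lead than in the other metals are thus no trait of a list. Hydroxycinnamoyl transferase (TA39333_4081, 1.18 ± 0.23) and caffeoyl-CoA O-methyltransferase (TA36557_4081, 1.28 ± 0.36), enzymes of lignin synthesis, rose in lead, as 2 of 8 phenylpropanoid genes (camera adjusted p = 0.0953). Of 8 WRKY factors, WRKY1 (LOC100301944) fell in mercury (-2.34 ± 0.43) and lead (-2.11 ± 0.43), with values of -1.72 and -1.5 without control 1. Of 8 proteinase inhibitors 1 fell in mercury and 2 in lead. Of 4 aquaporins 1 rose and 2 fell in mercury, with 0 past the test elsewhere (camera adjusted p = 0.245 in mercury). Of 17 histones 4 rose and 3 fell in lead, with H2B (TA56765_4081) at -2.35 ± 0.39.

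Of 3 genes of abscisic acid and dehydration 1 rose in lead, the dehydrin-like TC245073. Of 2 metal transporters 1 rose in cadmium and 1 in lead, and the measured ABC transporter (TA36448_4081) rose in mercury by 0.66 ± 0.19. Of 2 phosphate genes 1 fell in mercury, and of 3 UDP-glycosyltransferases 1 fell in mercury and 1 in lead. Of 2 iron genes 1 fell in chromium and 1 in mercury, and in lead 1 rose and 1 fell. Of 2 metallothioneins 1 fell in mercury, while the other had a higher value that did not pass, with a list median of 0. Both genes of phytochelatin and glutathione synthesis and all 3 tubulins stayed under the threshold in every metal, with tubulin medians of 0.08, 0.00, -0.30 and 0.41 in cadmium, chromium, mercury and lead. The array named 0 genes of multidrug and organic acid transport (MATE). Of 5 seed storage and oil body markers 1 rose and 1 fell in lead, vicilin (TA36972_4081) at -1.81 ± 0.33. The sign of the median, the mean and the camera test differed for expansins and extensins in cadmium, glutathione S-transferases, nitrate, WRKY and seed genes in chromium, jasmonate, WRKY, proteinase inhibitor, shoot and seed genes in mercury, and jasmonate, extensin, auxin and WRKY genes in lead, none past the camera threshold.

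Photosynthesis transcripts were high on the array of control 1. An exchange of the scanner file of control 1 with that of an array of a metal group was argued against, since 0 metal arrays followed the value table column of control 1 as closely as the other 12 arrays followed their own columns, although the scanner file of control 1 was closer to the column of cadmium 1 (0.963) than to its own. The Spearman's rho of 0.956 between the scanner file and the value table of control 1 is consistent with different hybridisations in them, and 2 instead of 30 of the 40 markers were above all other arrays in the value table, where chromium 2 had 19 and lead 1 had 10. Shoot tissue in the RNA of control 1 may be a candidate source and stays open, as 75% of the 40 markers were higher there than on every other array, short of the 80% set as the bound, with rubisco small chain 1 (TA35592_4081) at 6.11 against a mean of 0.62 and chlorophyll a-b binding protein 7 (TA36129_4081) at 2.48 against -2.83. The roots had no sort that would remove shoot cells, and exposure to light was not tested.

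The median of the heat shock list was lower in each metal than in the control. Under camera's preset correlation the array of control 1 alone is argued against, since without it the highest adjusted p of the list over the 4 metals was 0.00716. No fit without control 1 used an estimated correlation. With an estimated correlation and all arrays the list did not pass in cadmium (adjusted p = 0.155) or lead (0.083). For cadmium, chromium and mercury against the control the slide cannot be told apart from the metal. With the slide as a fixed block the medians were -0.28, -0.44 and -0.59 with 0.0142 as the highest camera adjusted p. Each rests on cadmium 1 alone, whose list median of 0.39 lay within the controls (0.37 to 0.71). Cadmium 1 had a heat shock median of 0.34 against the cadmium arrays on slide 2. Chromium 3, on slide 3, had -0.07 against the chromium arrays on slide 2. Within slide 2 cadmium against chromium had 0.25, and within slide 3 chromium against mercury had -0.06. For lead the slide cannot be told apart from the metal, because 0 arrays of another group lay on that slide. A response of the roots to the metals thus stays open as a hypothesis. In 9 of 100 regroupings of the arrays, the real one included, the list passed in as many comparisons (4, with 4 also the highest of the others and the most possible). Chance is not excluded by that count. Most of the other such regroupings kept control 1, often with a further control, in the place of the controls. They thus carry part of the real grouping, and the count says little about chance.

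More probes passed the threshold in lead than in the other metals. The scaling of the lead arrays is argued against, since over 3 other scalings the lead count stayed at least 3.15 times the highest count of the other metals. The array of control 1 alone is argued against for the order of the metals, since without it that ratio was 4.74. Slide 4, which held the lead arrays alone, cannot be told apart from the metal: arrays of one group on different slides gave at most 8 probes past the threshold, but with 1 array against 2 and none on slide 4 this leaves an effect of the slide open. The dose of lead, 194.4 mg/kg, was per the labels the same fraction of its median lethal concentration as for the other metals. Whether the dose played a part was not tested, as each metal had 1 dose.

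Other splits of the samples were counted for each limma result. For each pair of groups, 3 arrays against 3 allow 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) gave as many probes. The real and highest other counts were 349 and 0 for cadmium, 1097 and 0 for chromium, 2891 and 1 for mercury and 9699 and 6 for lead against control. Between metals they were 75 and 0 for cadmium against chromium, 2217 and 1 for cadmium against mercury, 437 and 0 for cadmium against lead, 3 and 0 for chromium against mercury, 3367 and 0 for chromium against lead and 9067 and 0 for mercury against lead. For the 4 metals together, 1 of 100 regroupings of the 15 arrays, the real one, gave as many as 4119. Another, with control 1, lead 1 and lead 3 in the place of the controls, gave 3969, which points to a structure of the samples. The regroupings ignored the slides, while all control arrays shared slide 1. A share of 1 in 100 therefore does not separate an effect of the metals from one of the slides. For any difference among the 5 groups (9139, highest other 135) and for probes shared by all 4 metals (190, highest other 0) the real grouping was again the 1 of 100. For the gene list tests, 20 of 100 regroupings gave at least 23 passing tests, with 33 as the highest, so chance is not excluded for the number of lists past camera's threshold.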
